A study of Homo sapiens with 2 samples.

How the data were processed

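Total RNA was measured in 2 samples of the human dermal fibroblast cell line DF, 1 untreated and 1 treated with PGE-2 for 6 h, both with a stranded total RNA library kit, per the labels' protocols. The deposited table holds raw read counts per gene symbol, 1 column per library and 23368 genes. According to the submitters' processing notes, Trimmomatic, TopHat2, Bowtie and HTSeq were used with the human build hg19, without versions. The annotation, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. The values were whole numbers with totals that differ between the columns, as raw counts have. All 23368 rows name a gene (0 rows name none), and 5473 rows were at 0 in both libraries. The columns were matched to the samples by their titles, and 0 columns belonged to other samples.

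The untreated library held 26497884 counts and the PGE-2 library 73064962, with 16582 and 17605 genes detected and 13190 and 14546 genes at 10 counts or more. The floor of 3 counts, the upper limit that a count of 0 allows, was 0.113 and 0.0411 CPM, the usual scaling of a count to its library total. No single gene dominated either library. The fibronectin gene FN1 took 3.25% and 2.93% of the counts and the top 10 genes 11.4% and 11.5%. The 9 genes found by mitochondrial symbol patterns took 0.236% and 0.233%, which need not be the whole share of mitochondrial RNA. Ribosomal protein genes took 3.11% and 3.30%, histone genes 0.0908% and 0.0903% and small RNA genes 0.156% and 0.187%.

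With 1 library per group no test with a spread between samples could be fitted, so edgeR and DESeq2 served for scale factors only. Counts were scaled by trimmed mean of M values (edgeR 4.0.16, R 4.3.3). The CPM of genes and lists use the library sizes scaled in this way, whereas the floor uses the plain totals. For each of the 14030 genes with at least 20 counts over both libraries, the ratio of the PGE-2 to the untreated library was given with the exact Clopper-Pearson 95% interval of the conditional binomial. A gene was counted as higher or lower when the whole interval lay beyond 2-fold. Where a library had 0 counts, the ratio was taken against 3 counts in that library, and its interval is open at 1 end. For each of 33 lists with at least 5 measured members, the median log2 ratio was set against the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression without the members, with a fixed seed, and a list stood apart when its median lay outside the central 95%. The lists held 737 genes, of which 736 were in the table and 628 had at least 20 counts. Several genes belong to more than 1 list, so the lists are not independent. An interval above or below 1 in the text is that of a member's ratio. Robust SDs are the scaled median absolute deviation across genes, which are not replicates. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used.

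The design, lists and alternatives were set before the data were examined. The rule for named genes took the 12 genes higher and the 12 lower whose interval bound lay farthest from no difference, leaving out small RNA genes, loci known only by a clone number and sex-linked genes that are not reported here. In each list that stood apart it took the 3 members farthest in the list's direction and the 1 farthest in the other direction where its interval lay there. It also took list members beyond 2-fold, which were 21 higher and 13 lower, and PTGER1, PTGER2, PTGER3, PTGER4, PTGS2, PRL and PRLR. A result that this rule would name is not reported here. Alternatives were other scalings (total counts, the median of ratios of DESeq2 1.42.0, upper quartile), other count minimums (1 and 100), an interval beyond 1.5-fold, a 99.9% interval, the ratio without an interval, the deeper library thinned at random to the total of the shallower, 0.5 or 2 added to every count, and 10 or 50 expression bins. Lists matched also on GC content and length, and the cytokine list without CXCL1, CXCL2, CXCL3, CXCL5, CXCL6 and IL8, were added after the data were seen.

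The gene reference was GENCODE release 29 on build GRCh38. It differs from hg19, so no coordinates are given, and it served for current names (22026 of 23368 symbols matched), for GC content and length of the longest transcript and for overlaps between genes. Of the 95 named genes, 34 overlap another annotated gene, mostly on the other strand. Reads of those are uncertain without the strand setting, and reads of genes that overlap on the same strand are uncertain under any setting. PTGER1 had no overlapping gene in this reference. IGF2, which overlaps the INS-IGF2 gene, was listed at 0 in both libraries, and its level is not read from that.

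The procedure was tested on simulated counts with the means and depths of these libraries. Over 14031 simulated genes, the rule called 100% of 45 genes changed 8-fold, 87.0% of 46 changed 4-fold and 75.5% of 49 changed 3-fold, and 0 of 49 changed exactly 2-fold. With counting error alone it called 0 of 13842 unchanged genes. With a spread between cultures of 10%, 20% and 40% (coefficient of variation) it called 0, 83 and 1963 unchanged genes, with robust SDs of the log2 ratio of 0.21, 0.42 and 0.86 at a mean of at least 10 CPM. Of 100 lists of randomly drawn unchanged genes, simulated with counting error alone, 2 fell outside the central 95%.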

Results

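Total RNA was sequenced from the human dermal fibroblast cell line DF, grown untreated or exposed to prostaglandin E2 (labelled PGE-2) for 6 h. Prostaglandin E2 is a lipid mediator made from arachidonic acid by the cyclooxygenases and a terminal synthase, and its receptors are encoded by PTGER1, PTGER2, PTGER3 and PTGER4. The series concerns COX-2, the inducible cyclooxygenase encoded by PTGS2, and prolactin signalling between tumour and stroma. The comparison therefore addresses which transcripts of a stromal cell differ after exposure to the product of that enzyme. Each condition holds 1 library. The untreated library held 26497884 counts over genes and the PGE-2 library 73064962, which is 2.76 times as many. No difference given here has a replicate check, so no p-value or SD is given, and each ratio compares these libraries and not the conditions. The 95% intervals cover counting error only, since the spread between cultures was not measured. They treat reads as independent, which reads without molecular identifiers need not be, so they can be too narrow even for that. They are widest for genes with few counts in the shallower untreated library. There a count of 0 allows a level of up to 0.113 CPM (a count scaled to its library total), against 0.0411 in the PGE-2 library. The CPM of genes and lists below use the library totals after scaling between the libraries, which differ slightly.

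The libraries were alike for most genes and far apart for a small set, with PRL, STAMBPL1, SST, IL33 and IL11 among the genes farthest above and OXTR and RNF128 among those farthest below. Of 14030 genes with at least 20 counts over both libraries, 70 were higher and 44 lower in the PGE-2 library with the whole counting interval beyond 2-fold, together 0.813% of the genes. The robust SD of the log2 ratio was 0.17 over the 7928 genes with a mean of at least 10 CPM and 0.67 over those under 1 CPM. Counting error left 7901 genes with an interval that includes a ratio of 1. Of the others, 3035 had an interval above 1 and 3094 below it, together 43.7% of the genes. A simulated spread between cultures of 10% gave 42.7% of unchanged genes an interval that excludes 1. Counts of list members above or below 1 are to be read beside these shares, which cover genes of all levels. Intervals are narrower for genes with more counts, so lists of abundant genes can exceed these shares without standing apart. The myofibroblast and TGF-beta list, within the random range, had 11 of 28 above 1 and 12 below. No share matched on level was computed. Among 33 gene lists fixed before the data were examined, 11 had a median log2 ratio above the central 95% of random lists matched on mean expression. Another 6 had a median below it, where 1.65 lists in all would lie outside if list members were random draws of genes. Related genes can vary together between any 2 cultures, so that number is not what a difference between untreated cultures would give. The list positions describe the 2 libraries. The genes CISH, PTGS1, AXIN2, ACTA2, IGFBP1 and KDR were chosen after their values were seen.

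**Figure D1:**
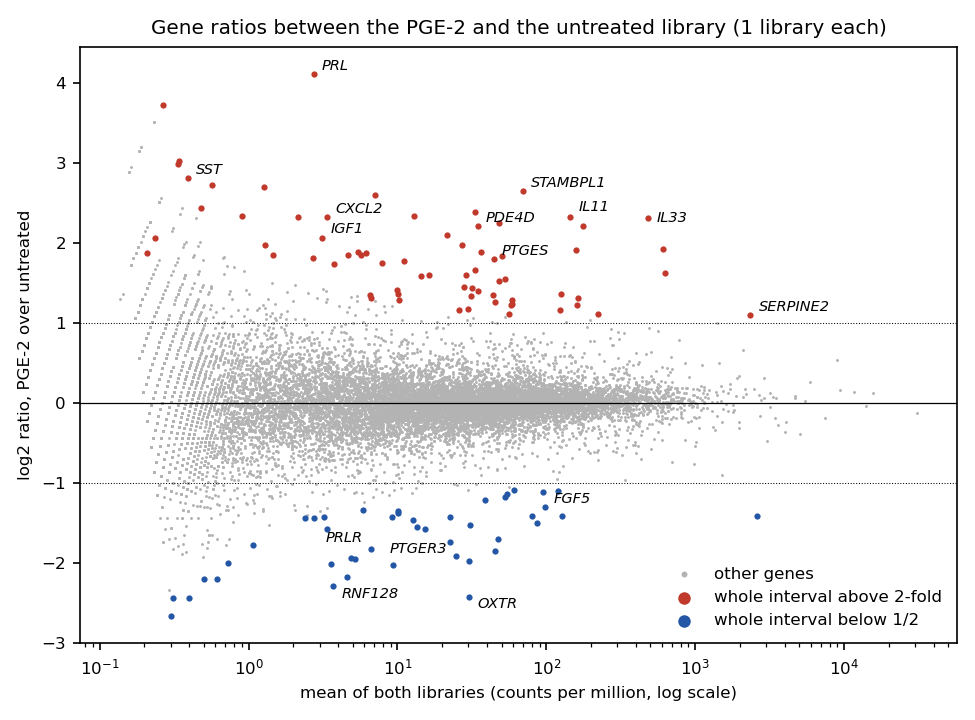
Log2 ratio of the PGE-2 over the untreated library (vertical axis) against the mean of both libraries in CPM (log scale), 1 point per gene. Red and blue points are the 70 higher and 44 lower genes whose whole 95% counting interval lies beyond 2-fold (dotted lines), and the spread of the grey points widens toward low counts.

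Prolactin is a hormone of the pituitary and of some cells outside it. Among the named genes, its transcript had the interval bound farthest from no difference. PRL had 8 counts in the untreated library and 375 in the PGE-2 library, a 17.2-fold higher level with an interval from 8.66-fold to 40.2-fold. Its level in the PGE-2 library was 5.17 CPM. The transcript of its receptor was lower, with 278 counts for PRLR in the untreated library against 214 in the deeper PGE-2 library, a ratio 3.53-fold lower (2.95 to 4.24). The list of prolactin and JAK2-STAT5 signalling genes had a median log2 ratio of 0.34 and stood above random lists. Of its 15 measured members, 10 had an interval above 1, 2 below it and 3 including it. SOCS2, a feedback inhibitor of cytokine receptors that STAT5 induces, was 2.34-fold higher (2.18 to 2.51), and the growth factor gene IGF1 was 4.18-fold higher (2.91 to 6.21) from 32 and 364 counts. CISH, another STAT5 target, had 10 and 18 counts and an interval that includes 1.

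Transcripts of prostaglandin receptors lay in both directions. PTGER3, which encodes the receptor coupled to inhibitory G proteins, was 3.75-fold lower in the PGE-2 library (3.41 to 4.12), from 1041 and 755 counts. PTGER4 was 1.92-fold lower (1.36 to 2.68) from 62 and 88 counts, whereas PTGER2 was 1.36-fold higher (1.22 to 1.52) from 417 and 1548 counts. Both encode receptors that raise cyclic AMP. PTGER1 was listed at 0 in both libraries. The median of the 7 measured prostanoid receptors, at -0.24, lay within the range of random lists, although it lay below that range at -0.34 over the 6 members with at least 100 counts. On the synthesis side PTGES, the inducible terminal synthase of prostaglandin E2, was 3.47-fold higher (3.17 to 3.80). PTGS2 was 1.59-fold higher (1.5 to 1.7) with 1401 and 6050 counts, and the constitutive cyclooxygenase gene PTGS1 was 1.82-fold higher. The median of the 16 genes of prostaglandin synthesis, transport and breakdown was 0.06, within the random range, with 7 intervals above 1, 1 below it and 8 including it. Over the 14 members with at least 100 counts it was 0.18, above random lists.

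Genes known to respond to cyclic AMP through the transcription factor CREB were higher as a group. The median log2 ratio of this list was 0.44, and of 33 measured members 21 had an interval above 1, 5 below it and 7 including it. SST, the somatostatin gene, had 0 counts in the untreated library and 57 in the PGE-2 library. It was 6.98-fold higher against the floor of 3 counts, with an interval that starts at 5.50-fold and has no upper end. With 2 added to every count its log2 ratio was 3.44 in place of 2.80. CREM, which encodes activators and an inducible repressor of cyclic AMP-responsive transcription, was 3.17-fold higher (2.86 to 3.51), and the nuclear receptor gene NR4A3 was 3.61-fold higher (2.80 to 4.72). GADD45A lay the other way, 1.57-fold lower (1.42 to 1.73). Cyclic AMP phosphodiesterases, the enzymes that break the messenger down, had a median of 0.28 and also stood above random lists, with 6 of 13 members above 1, 2 below and 5 including it. PDE4D was 4.62-fold higher (4.13 to 5.19) from 328 and 4122 counts, PDE7B 1.63-fold and PDE4B 1.61-fold, while PDE1C was 1.38-fold lower (1.2 to 1.6). PDE4D, PDE7B and PDE4B belong to the CREB target list too, so the lists are not separate. The 20 adenylyl cyclase and protein kinase A genes had a median of 0.06 within the random range, with 13 intervals including 1. The 16 regulators of G protein signalling had a median of -0.11 within it, although RGS4 was 3.95-fold lower (3.62 to 4.30).

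Several of the genes farthest above no difference belong to none of the lists. STAMBPL1, which encodes a deubiquitinase, was 6.26-fold higher (5.73 to 6.86) from 511 and 8708 counts. The receptor gene GPRC5A was 6.07-fold higher (4.60 to 8.17), FAM167A 5.23-fold (4.64 to 5.93) and the spermine oxidase gene SMOX 5.03-fold (4.16 to 6.13). C13orf33, now called MEDAG and known from adipocyte differentiation, was 4.61-fold higher (4.39 to 4.85), and SPON1, which encodes the matrix protein F-spondin, 4.29-fold (3.73 to 4.95). SPON1 has an annotated antisense gene, as PDE4D has, and with the strand setting of the counting not given in the sources used here their reads cannot be parted from it. Of the 95 named genes, 34 overlap another annotated gene, and the same uncertainty holds where that gene lies on the other strand. GPRC5A, FGF5, CXCL6, TGFB2 and ECSCR overlap a gene on their own strand, so their reads are uncertain under any strand setting.

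At the other end, OXTR, the oxytocin receptor gene, was 5.39-fold lower in the PGE-2 library (4.91 to 5.91), from 1354 and 684 counts. The ubiquitin ligase gene RNF128 was 4.87-fold lower (3.75 to 6.37), and GRB14, whose product binds the insulin receptor, 4.52-fold lower (3.59 to 5.71). CNIH3 was 4.06-fold lower (3.47 to 4.75), MALL 3.26-fold (3.05 to 3.48) and KRTAP1-5, a member of a family of similar keratin-associated genes among which reads can be misassigned, 3.88-fold (3.14 to 4.79). The adhesion receptor gene ICAM1 was 3.83-fold lower (3.09 to 4.77) from 207 and 147 counts, and E2F7, which encodes a repressor of cell cycle genes, 3.34-fold lower (3.03 to 3.68).

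**Figure D2:**
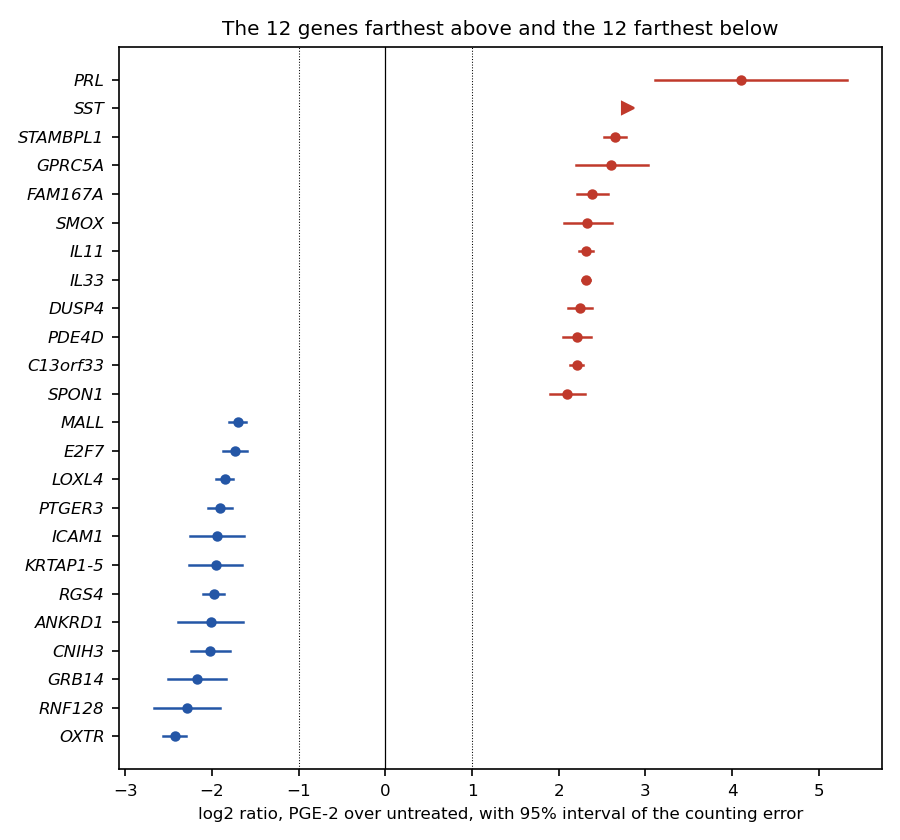
Log2 ratio of the PGE-2 over the untreated library for the 12 genes farthest above and the 12 farthest below no difference, ranked here by ratio, 1 library each. Horizontal bars are 95% intervals of the counting error and dotted lines mark 2-fold. The arrowhead for SST stands at its ratio against 3 counts, because the untreated library had 0 counts. Its interval, not drawn, starts at 2.46 and has no upper end. The interval of PRL runs from 3.11 to 5.33.

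The cytokine and chemokine list stood above random lists, with a median log2 ratio of 0.54 over 19 measured members. Of these, 10 had an interval above 1, 6 of them wholly beyond 2-fold, against 1 below 1 and 8 including it. IL33, an alarmin of barrier tissues, was 4.96-fold higher (4.81 to 5.12) from 4340 and 58611 counts, and IL11 was 4.98-fold higher (4.71 to 5.28) from 1282 and 17372 counts. The neutrophil chemokine genes CXCL2, CXCL1, CXCL6 and CXCL3 were 5.0-fold, 3.71-fold, 3.58-fold and 3.36-fold higher. They are close relatives of each other, so reads that fit several of them are uncertain. Without CXCL1, CXCL2, CXCL3, CXCL5, CXCL6 and IL8 the list no longer stood apart, at a median of 0.16 over 13 members, with 5 intervals above 1, 1 below it and 7 including it. IL6 was 1.51-fold lower (1.25 to 1.82), from 178 and 320 counts. The feedback targets of NF-kB, a transcription factor that drives many of these cytokines, had a median of -0.15 within the random range, with 5 of 20 above 1 and 10 below it, and lay just under that range at -0.16 over the 17 members with at least 100 counts. The 26 interferon-stimulated genes had a median of -0.03, within the random range, with 8 above and 8 below 1. OAS1 was the exception beyond 2-fold among them, 3.94-fold higher (2.28 to 7.38) from 14 and 150 counts.

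The growth factor list stood above random lists with a median of 0.50, and of 34 measured members 18 had an interval above 1, 9 below it and 7 including it. Besides IGF1, the stanniocalcin gene STC1 was 2.57-fold higher (2.45 to 2.70) and INHBA, which encodes the subunit of activin A, 2.47-fold (2.37 to 2.58). FGF5 was 2.46-fold lower (2.35 to 2.57). Targets and ligands of the Wnt pathway had a median of 0.15, above random lists, with 10 of 21 above 1 and 6 below. The members farthest above were a ligand, a secreted inhibitor and a matricellular gene: WNT5A was 1.84-fold higher (1.79 to 1.89), SFRP4 2.5-fold (2.0 to 3.2) and WISP1 1.68-fold (1.61 to 1.75). LEF1 was 2.25-fold lower (1.52 to 3.29), and AXIN2, a common direct target of beta-catenin, had an interval that includes 1 from 124 and 292 counts.

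Markers of decidualization, the cyclic AMP-driven differentiation of uterine stromal cells, had a median of 0.48 and stood above random lists, with 12 of 22 above 1, 4 below and 6 including it. PRL and SST belong to this list too. BMP6 was 1.85-fold higher (1.63 to 2.10) and TIMP3, an inhibitor of metalloproteinases, 1.30-fold lower. IGFBP1, a further marker of that state, had 6 counts in the untreated and 7 in the PGE-2 library, too few to compare.

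Matrix genes were slightly higher as a group, with a median log2 ratio of 0.13 over 36 genes of fibrillar collagens and matrix, 25 of them above 1, 7 below and 4 including it. The thrombospondin genes THBS2 and THBS1 were 2.0-fold (1.97 to 2.02) and 1.45-fold (1.44 to 1.45) higher and P4HA3, a subunit of a collagen prolyl hydroxylase, 1.93-fold higher (1.72 to 2.18), whereas LOXL4, a collagen cross-linking oxidase, was 3.62-fold lower (3.38 to 3.88). The fibroblast identity list had a median of 0.19, above random lists, with 16 of 23 above 1 and 3 below. TWIST2 was 2.31-fold higher, COL6A1 and LRP1 each 1.27-fold higher and PDGFRB 1.47-fold lower (1.44 to 1.51). Several collagen genes belong to both lists. Targets of YAP-TEAD and SRF, transcription factors that respond to cell tension, were lower with a median of -0.19, and 15 of 24 lay below 1 against 5 above. ANKRD1 was 4.04-fold lower (3.13 to 5.24), TGFB2 1.61-fold (1.32 to 1.95) and the focal adhesion gene VCL 1.38-fold (1.35 to 1.40), with DLC1 1.17-fold higher. Myofibroblast and TGF-beta targets had a median of -0.04 within the random range, 11 of 28 above and 12 below 1. ACTA2, the smooth muscle actin gene, was 1.33-fold lower.

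Hyaluronan and protease genes showed no common direction, with a median of -0.01 over 30 members, 7 above 1 and 12 below. The hyaluronan synthase gene HAS1 was 3.65-fold higher (2.86 to 4.73). The serine protease inhibitor gene SERPINE2 was 2.13-fold higher (2.11 to 2.16) from 39968 and 232120 counts.

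Genes of DNA replication and division were lower in the PGE-2 library. The median of the S phase list was -0.50, and 30 of 34 members had an interval below 1, with 4 including it and 0 above. The cyclin gene CCNE2 was 2.94-fold lower (2.60 to 3.33), and the replication licensing genes MCM10 and CDC6 were 2.26-fold (1.90 to 2.67) and 2.18-fold (1.93 to 2.47) lower. The G2 and M phase list had a median of -0.37, with 31 of 37 below 1 and 5 including it. The proliferation marker MKI67 was 1.53-fold lower (1.41 to 1.66), the spindle gene TPX2 1.43-fold (1.33 to 1.54) and the mitotic kinase gene PLK1 1.64-fold (1.30 to 2.06). CCNA2 was the member above 1, at 1.14-fold higher (1.1 to 1.2). The 19 p53 targets had a median of 0.01, within the random range, with 5 above 1 and 9 below. ERK feedback and immediate early genes were lower with a median of -0.14, 11 of 25 below 1 and 7 above. DUSP6 was 1.68-fold (1.54 to 1.82), EPHA2 1.69-fold (1.44 to 1.98) and SPRY4 1.53-fold (1.43 to 1.64) lower. DUSP4, another MAP kinase phosphatase of that list, was 4.75-fold higher (4.31 to 5.24).

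Cholesterol synthesis genes were lower, with a median of -0.19 and 12 of 22 below 1 against 2 above. MVK was 2.54-fold lower (1.96 to 3.30) from 116 and 124 counts, HMGCS1 and MSMO1 were each 1.55-fold lower and STARD4, a sterol carrier, was 1.38-fold higher (1.31 to 1.46). Hypoxia and glycolysis genes were higher with a median of 0.14, 16 of 22 above 1 and 6 below. PFKFB3, a regulator of glycolytic flux, was 1.57-fold higher (1.46 to 1.68), VEGFA 1.52-fold (1.46 to 1.58) and ADM 1.42-fold, and the hexokinase gene HK1 was 1.2-fold lower (1.17 to 1.25). Stress and clock lists lay within the random range in the main comparison, and heat shock lay just above it with no count minimum, with 10 expression bins and with lists matched on GC content and length. The integrated stress and unfolded protein response list had a median of -0.04 over 26 genes, the heat shock list 0.12 over 14 and the circadian clock list 0.08 over 15. The amino acid transporter gene SLC7A5, on the stress list, was 2.55-fold higher (2.35 to 2.77).

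The marker lists of cell types other than fibroblasts differed in level and direction. Summed levels in the untreated and the PGE-2 library were 203 and 168 CPM for pericyte and smooth muscle markers, 98.4 and 97.8 CPM for keratinocyte and epithelial markers, 36.7 and 38.1 CPM for leukocyte markers and 6.04 and 4.27 CPM for melanocyte and Schwann cell markers. The endothelial list was lower, with a median of -0.73 over 8 measured markers whose summed level was 43.6 CPM in the untreated and 29.1 in the PGE-2 library. Without FLT1 the other 7 summed to 9.86 and 12.5 CPM, so the lower sum rests on that gene. Its members went both ways, with 2 intervals above 1, 2 below it and 4 including it. ERG was 6.35-fold lower (2.29 to 20.2) from 14 and 6 counts and FLT1 2.03-fold lower (1.86 to 2.22), ECSCR had 16 and 24 counts with an interval including 1, and TEK and KDR were 1.95-fold (1.52 to 2.52) and 2.06-fold higher. The adipocyte list was higher with a median of 0.69 over 7 markers, 3 of them above 1 and 4 including it, at summed levels of 18.4 and 24.8 CPM. LEP was 3.27-fold higher (1.64 to 7.41) from 9 and 80 counts, G0S2 2.51-fold (1.99 to 3.21) and PNPLA2 1.61-fold (1.23 to 2.15). This list was no longer apart, at a median of 0.14, when genes with fewer counts entered. Markers of keratinocytes and epithelium (median -0.21 over 8), leukocytes (0.02 over 10), pericytes and smooth muscle (-0.13 over 14) and melanocytes and Schwann cells (-0.49 over 6) lay within the random range, although the pericyte list lay below it at -0.22 over the 12 members with at least 100 counts. Among them KRT19, DES and NGFR were lower beyond 2-fold, from 44 and 35, 108 and 108, and 14 and 7 counts. With the deeper library thinned to the total of the shallower, KRT19 and DES were no longer beyond 2-fold, at log2 ratios of -1.19 and -1.34, and NGFR and ERG fell under the count minimum.

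**Figure D3:**
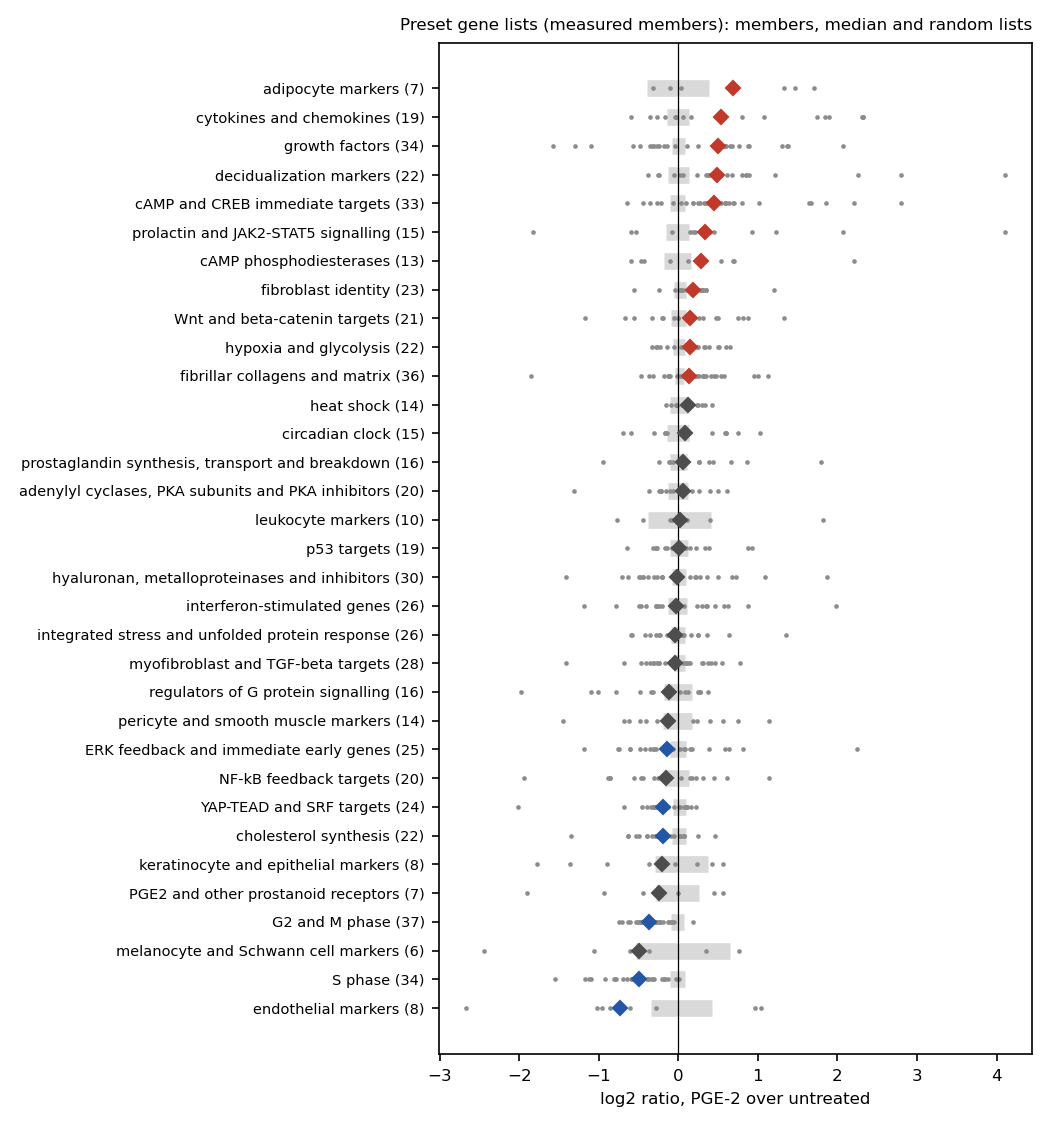
Log2 ratio of the PGE-2 over the untreated library for the members (small grey points), the median (diamond) and the central 95% of medians of 10000 random lists matched on mean expression (grey bar) of each of the 33 lists, with the number of measured members in parentheses and 1 library each. Red diamonds mark the 11 lists above that range and blue diamonds the 6 below it, from adipocyte markers at 0.69 to endothelial markers at -0.73.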

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

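The lists matched on GC content and length and the cytokine list without CXCL1, CXCL2, CXCL3, CXCL5, CXCL6 and IL8 were chosen after the data were seen. The numbers of genes beyond 2-fold, 70 higher and 44 lower, stayed within 1.5 times under the other scalings (66 to 70 and 44), count minimums (62 to 70 and 37 to 50) and with the deeper library thinned (66 and 39, of which 62 and 34 were among the original genes). Dropping the interval gave 346 and 218 genes, a lower threshold of 1.5-fold 196 and 161, and a wider interval 51 and 29, each as those rules are built. The largest shift of a named log2 ratio under another scaling was 0.02. With 2 added to every count it was 0.63, for SST, and PRL stood at 3.79. With thinning it was 0.58, for KRT19. Thinning kept 27 higher and 16 lower named genes beyond 2-fold and lost KRT19, DES, ERG and NGFR. No list that stood apart and no named gene with an interval excluding 1 changed sign. The medians near 0 of p53 targets (-0.01 with total counts, -0.05 with a minimum of 100) and leukocyte markers (with total counts, with no minimum and, at -0.02, with 0.5 added) did. The adipocyte list lost its position with no count minimum, at a median of 0.14 over 11 members, because members with few counts entered. The cytokine list lost its position without the CXCL genes and IL8, at 0.16 over 13 members. The other lists that stood apart kept their side under the alternatives run, except that the endothelial and adipocyte lists, with the keratinocyte, leukocyte and melanocyte lists, had under 5 members with 100 counts and were not run there. Some lists not apart moved outside the random range: prostanoid receptors at -0.34 with no minimum and with a minimum of 100 counts, prostaglandin synthesis at 0.18, NF-kB feedback at -0.16 and pericyte markers at -0.22 with that minimum, NF-kB feedback at -0.15 with GC and length matched, and heat shock at 0.12 with no minimum, with 10 bins and with GC and length matched. The cause was not tested. The untreated library limits the precision for genes with few counts, and the spread between cultures stays unmeasured. Simulated spreads of 10%, 20% and 40%, drawn separately for each gene, called 0, 83 and 1963 unchanged genes. Their robust SDs at a mean of at least 10 CPM were 0.21, 0.42 and 0.86, against 0.17 between these libraries. All 3 settings were thus wider than these libraries over most genes, although single genes can vary more.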

Other observations

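Of the tests in this part, the one on the cytokine list without its CXCL genes and the lists matched on GC content and length were chosen after the data were seen. The genes of this paragraph and the next lie outside the lists and were chosen after their values were seen, among those with a whole interval beyond 2-fold. TFPI2, a secreted protease inhibitor, was 3.77-fold higher in the PGE-2 library (3.68 to 3.87) from 6812 and 69929 counts, and TM4SF1 was 3.92-fold higher (3.48 to 4.43). The neurotrophin receptor gene NTRK2 was 6.49-fold higher (3.34 to 14.5) from 9 and 159 counts, the endothelin receptor gene EDNRB 3.60-fold (2.72 to 4.86), the cation channel gene TRPC6 3.41-fold (2.85 to 4.10) and CXCR7, now called ACKR3, 2.86-fold (2.64 to 3.11). PPP1R3C, which directs a phosphatase to glycogen, was 3.07-fold higher (3.0 to 3.1), and the transcription factor gene KLF9 3.0-fold (2.6 to 3.5). The long non-coding RNA LINC00473, known as a target of cyclic AMP signalling, had 0 and 30 counts. It was 3.68-fold higher against 3 counts, with an interval that starts at 2.81-fold and has no upper end.

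Among genes lower in the PGE-2 library were NPR3, the natriuretic peptide clearance receptor, at 2.67-fold lower (2.54 to 2.81) from 3103 and 3163 counts, and CMKLR1, the chemerin receptor, at 2.99-fold lower (2.32 to 3.84). The transcription factor gene MEF2C was 2.98-fold lower (2.66 to 3.35) and the water channel gene AQP1 2.32-fold lower (2.16 to 2.49). TXNIP, an inhibitor of thioredoxin, was 2.20-fold lower (2.07 to 2.34). DTL, which acts in replication control, was 2.75-fold lower (2.43 to 3.13).

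The S phase and the G2 and M phase lists were lower in the PGE-2 library, with medians of -0.50 and -0.37. For the S phase list, the central 95% of random lists matched on mean expression reached down to -0.11, so genes of like level shifted less. That is the comparison by which the list stood apart. It is therefore no separate test of an abundance-dependent shift between libraries of unequal depth. GC content and transcript length bias is argued against for both, since lists matched on these too reached down to -0.12 for S phase and -0.11 for G2 and M phase. The hypothesis that fewer cells were cycling after PGE-2 treatment cannot be told apart from any other difference between the 2 cultures, such as density, because each group has 1 library.

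Prolactin transcript was higher in the PGE-2 library, at 375 counts against 8. RNA from pituitary tissue is argued against, since the other pituitary genes tested (GH1, POU1F1, LHB, TSHB and FSHB) had 7 counts summed in that library. Reads from an overlapping gene are argued against as well, with 0 genes whose exons overlap PRL in the reference used. That PGE-2 raises PRL in these cells, possibly through the cyclic AMP pathway whose target list was also higher, stays a hypothesis: PGE-2 treatment and any other difference between the 2 cultures cannot be told apart with 1 library per group.

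The cytokine and chemokine list was higher while the NF-kB feedback list was not, a difference of 0.69 between their medians. The same difference between random lists matched on mean expression reached 0.21 at the upper end of its central 95%. Both lists had already been placed by random lists of that kind, so this is no separate test of an abundance-dependent shift. Reads shared between near-identical CXCL genes stay open, because the list without CXCL1, CXCL2, CXCL3, CXCL5, CXCL6 and IL8 had a median of 0.16, within the random range, and misassigned reads and real regulation of these genes would both give that. No biological explanation was tested for this pattern.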
